A study of Homo sapiens with 4 samples.

How the data were processed

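Each of the 4 samples is 1 two-colour array with total RNA of 5-Aza-treated MCF-7 cells in 1 channel and of untreated MCF-7 cells in the other. Per the labels' protocols, DNase-treated total RNA was amplified and labelled with Agilent's linear amplification kit for low RNA input. The dose, the length of treatment and the solvent are not given in the sources used here. The dyes in the labels set the direction of each ratio. Per the file headers, all 4 arrays lie on 1 slide and were scanned together, so no slide or scan batch separates them, and the spots were read with Agilent Feature Extraction 9.5.1.1 (version 9.5 per the submitters' processing notes).

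The deposited scanner files hold the mean intensity and the median local background intensity of each spot for Cy3 and Cy5, on a linear scale and not normalized. Per the file headers, they also hold processed intensity values, which the software had background-subtracted with spatial detrending and dye-normalized by LOWESS, and the log10 ratio of processed Cy5 over Cy3. The authors' series table holds 24581 spots, of which 12328 probes had values on every array. Set against the scanner's log10 ratios, the deposited values were log2 ratios of treated over untreated cells, with slopes of -3.32 to 3.33 that changed sign with the dye orientation. The column medians were -0.02, 0.05, 0.00 and 0.06 for arrays 1 to 4, so the columns were close to centred on 0. The rule by which the authors selected rows is not given in the sources used here.

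Ratios were recomputed in R 4.3.3 with limma 3.58.1. Mean signals were corrected for background by normexp with an offset of 50, which draws the ratios of dim probes toward 0, and normalized by loess within each array with control spots at weight 0. The 1417 control spots were left out, as were 618 probes with an outlier flag on any array. Ratios were turned to treated over untreated. A probe was tested if it was well above background, by the scanner software's call, on all 4 arrays in at least 1 of the 2 RNAs. Since the labels give 2 biological and 2 technical replicates but not which arrays belong together, arrays were averaged in pairs of opposite dye, in which a dye effect cancels. That technical replicates were dye swaps is an assumption, and the labels leave open that arrays of the same dye orientation share RNA. Both possible pairings (arrays 1 with 2 and 3 with 4, and arrays 1 with 4 and 2 with 3) were fitted with lmFit and eBayes, each probe took the higher p, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The SD of the contrast between pairs was 0.097 for the first pairing and 0.108 for the second, against 0.152 between the 2 dye orientations, and so did not settle which arrays share RNA. The prior degrees of freedom were 10.4 for the first pairing and infinite for the second, so in the second all probes share 1 estimate of the spread. Fold changes are the mean of 4 arrays with the SD over the 4 arrays.

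The test was run on simulated data with 14371 probes, of which 200 per run changed by known folds, in 3 runs with the measured spread between arrays, shared in equal parts between the arrays of a pair and single arrays. It called 95.3% of simulated 1.5-fold changes and 100% of 2-fold, 4-fold and 8-fold changes, and 8.63% of all its calls were unchanged probes, above the 5% aimed for. The simulation held far fewer changes than were called in the data and none under 1.5-fold. It let arrays 1 and 2, and 3 and 4, share RNA. Its shares therefore do not carry over to smaller changes or to other sharing of RNA. A probe not well above background on any array of a condition has only a bound on its fold. The bound sets the mean log2 level of the brighter RNA over 4 arrays against that of the dimmer RNA, in which each array takes the higher of the probe's own level and the lowest level among probes well above background, per channel after loess and Aquantile normalization. Where the probe's own level is the higher on every array, the bound is only the measured ratio.

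Before the data were examined, the rule for named genes took the 12 highest and 12 lowest mean log2 ratios among genes past the threshold and changed in the same direction on all 4 arrays. It also covered members of 22 gene lists, a few genes of interest such as DNMT1 and ESR1, and probes annotated as non-coding. The scanner files give each probe an array-specific ID, a sequence and no gene or position, so the rule was applied to probes, the first 2 in each direction are named, and the others are summarised. The gene lists and the comparison of non-coding with coding probes were not run.

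Alternatives fixed beforehand were all 4 arrays with and without a dye term, each pairing alone and the pairing of equal dye orientation, the scanner software's processed signals, no background correction, median centring, Aquantile normalization, no filter and a stricter filter on dim probes, eBayes with trend and robust settings, the authors' values, a 2-fold cut-off, an analysis with arrays 1 and 2, and 3 and 4, as blocks, and leaving out each array. Chosen after the data were seen were the highest p of all 3 pairings, a correction for GC content, no normalization within arrays, a block without a dye term, and everything on probes of opposite strands, which were paired where 1 probe's sequence is the exact reverse complement of the other's. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.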

Results

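RNA from MCF-7 cells, an oestrogen receptor-positive human breast cancer line, was compared between cells exposed to 5-Aza-2'-deoxycytidine (5-Aza) and untreated cells. 5-Aza is a cytidine analogue that is built into DNA and traps DNA methyltransferases, so that methylation is lost as cells divide. Treated and untreated RNA were hybridised together on each of 4 two-colour Agilent arrays of 1 slide, which carry 43803 probes of 60 bases beside the control spots. The treated RNA carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4. The series describes 2 biological and 2 technical replicates, and the labels do not say which arrays share RNA. The scanner files pair no probe with a gene name, so the results below concern probes, and genes and non-coding classes were not analysed here.

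Between 31.0% and 71.1% of probes were well above background in the treated RNA of an array, and between 33.6% and 62.4% in the untreated RNA. Array 4 had the highest share for both RNAs. On each array the RNA in Cy5 had the higher share, so which RNA had more probes well above background followed the dye. On all 4 arrays, 12807 probes, or 29.2%, were well above background in both RNAs. A total of 14371 probes were well above background on all 4 arrays in at least 1 of the 2 RNAs and were tested. The number of arrays limits the precision of each value. The log2 ratios of 5-Aza over untreated correlated across tested probes with r of 0.58 to 0.78 between arrays, and probes are not independent replicates. The 2 pairs of arrays with the same dye orientation correlated at 0.77 and 0.78, and the pairs of opposite orientation at 0.58 to 0.71. Where the same sequence was printed as 2 probes and both were tested, as for 49 sequences, the 2 mean log2 ratios differed by a median of 0.03.

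**Figure D1:**
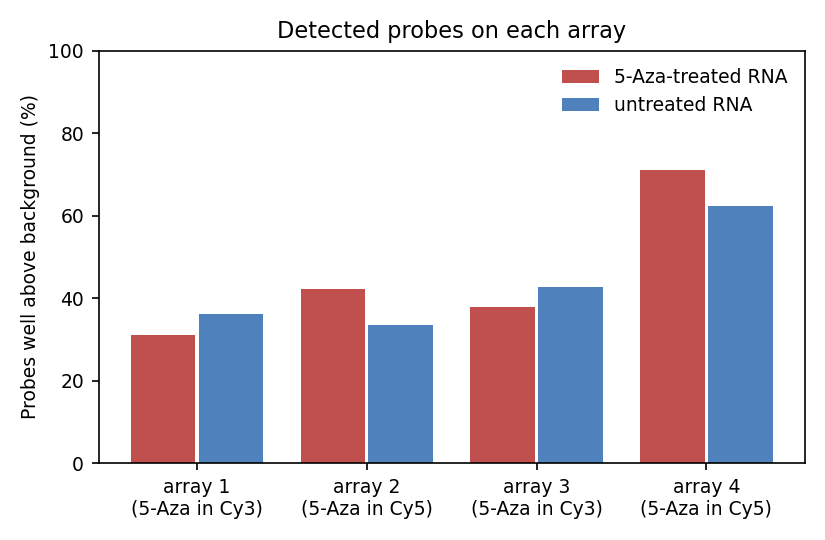
Share of the 43803 probes called well above background by the scanner software (y axis, percent), for the 5-Aza-treated RNA (red bars) and the untreated RNA (blue bars) on each of the 4 arrays (x axis, with the dye of the treated RNA). On array 4 the shares were 71.1% and 62.4%, against at most 42.1% and 42.7% on the other arrays.

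The comparison of treated with untreated cells asked which transcripts change when cells are exposed to the demethylating agent. Large rises outnumbered large falls. At least 2-fold changes past the threshold were seen for 230 probes that rose and 75 that fell, and at least 4-fold changes for 45 that rose and 1 that fell. Of the probes that rose, 20 did so by 8-fold or more. With signals processed by the scanner software in place of the correction used here, rises were 65.0% of the changes of 2-fold or more, against 75.4%, and 179 probes fell by at least 2-fold, while 49 did so without normalization within arrays. Each of the 305 changes of 2-fold or more also passed the threshold, in the same direction, when any 1 array was left out. Those fits had a dye term and counted single arrays as replicates, unlike the main test. Since the 305 were picked for large mean ratios on the same arrays, this is no independent support.

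Smaller changes were frequent and, after loess normalization, balanced in direction. In all, 2439 probes rose and 2216 fell, which was 32.4% of those tested, at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, each probe carrying the higher p of the 2 pairings in which arrays of opposite dye share RNA. Among these 4655 probes, 3537, or 76.0%, changed by less than 1.5-fold. The median was 1.34-fold for probes that rose and 1.33-fold for those that fell. Of all tested probes, called or not, 5984, or 41.6%, had the same direction on all 4 arrays, and 4117 of the 4655 did so. Unchanged probes on independent arrays would do so in 12.5% by chance. Arrays that share RNA are not independent, which can raise that share. The 4117 are no separate support, since the calls rest on the same ratios. The number of small changes depended on the setting: with arrays of the same dye orientation paired, which the labels do not rule out as the true pairing, 1419 probes rose and 1222 fell, and with no filter on dim probes 538 rose and 302 fell. Without normalization within arrays, which raised the median log2 ratio of tested probes from 0.02 to 0.11, 1582 rose and 593 fell, so the balance of directions depends on the centring. Nothing in the labels says that the 4 arrays stem from separate cultures beyond the 2 biological replicates, so p-values measure a spread that is in part technical.

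**Figure D2:**
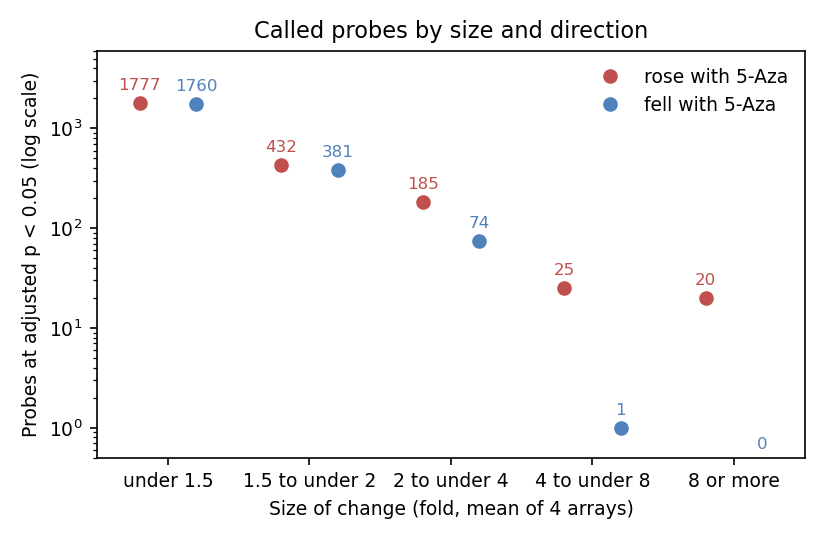
Number of probes at an adjusted p under 0.05 (y axis, log scale) by the size of the change, taken from the mean log2 ratio of 4 arrays (x axis, fold), for probes that rose (red) and fell (blue) with 5-Aza. Under 1.5-fold the numbers were 1777 and 1760, from 2-fold to under 4-fold they were 185 and 74, and at 8-fold or more they were 20 and 0.

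The 12 probes with the largest rises had mean log2 ratios of 3.31 to 5.00, or 9.89-fold to 32.1-fold. Their adjusted p was at most 5.17e-09, and 8 of the 12 were well above background in both RNAs on all 4 arrays. The probe ge_Q1_P06025, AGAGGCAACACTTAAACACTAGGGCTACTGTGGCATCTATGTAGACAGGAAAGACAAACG, had the highest ratio, a log2 ratio of 5.00 ± 0.22 (SD, n = 4; limma adjusted p = 4.95e-11), and was well above background in both RNAs on all 4 arrays. The probe ge_Q1_P00289, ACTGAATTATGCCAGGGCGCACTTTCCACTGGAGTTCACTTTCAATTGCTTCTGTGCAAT, rose by 4.48 ± 0.28 (SD, n = 4; limma adjusted p = 4.95e-11) on the log2 scale, and was likewise measured in both RNAs on each array. With processed signals its log2 ratio was 5.11.

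The 12 probes with the largest falls had mean log2 ratios between -2.79 and -1.42, or 6.91-fold to 2.68-fold lower in treated cells, with limma adjusted p of at most 6.18e-07. Of these 12, 8 were well above background in both RNAs on all 4 arrays. The probe ge_Q1_P03012, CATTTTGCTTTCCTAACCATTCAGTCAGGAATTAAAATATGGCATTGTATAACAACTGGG, had a log2 ratio of -2.79 ± 0.18 (SD, n = 4; limma adjusted p = 7.53e-10) and with the processing used here was the 1 probe with a fall of 4-fold or more. The probe ge_Q1_P08983, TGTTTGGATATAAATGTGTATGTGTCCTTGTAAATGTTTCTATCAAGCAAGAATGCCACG, had a log2 ratio of -1.85 ± 0.48 (SD, n = 4; limma adjusted p = 3.03e-08). In treated cells it was well above background on 2 of 4 arrays. Its 2 values with treated RNA in Cy3 were -2.34 and -2.18, and its 2 values with treated RNA in Cy5 were -1.46 and -1.41. With the scanner's processed signals, and in the authors' deposited table, the mean log2 ratio of ge_Q1_P08983 was -3.42, below that of ge_Q1_P03012 at -3.31, so the order and size of these 2 falls depend on how the signals were processed.

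**Figure D3:**
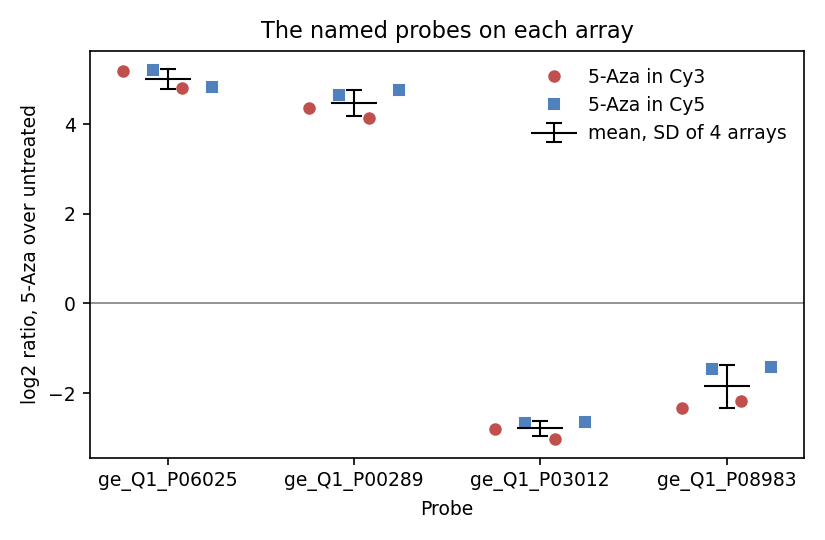
Log2 ratio of 5-Aza over untreated cells (y axis) of the 2 probes with the largest rises and the 2 with the largest falls (x axis), with 1 point per array, circles for treated RNA in Cy3 and squares for treated RNA in Cy5. The bar and whiskers give the mean and the SD of 4 arrays, from 5.00 ± 0.22 for ge_Q1_P06025 to -2.79 ± 0.18 for ge_Q1_P03012.

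Some probes were well above background in only 1 of the 2 RNAs. There were 19 probes well above background on all 4 arrays in treated cells and on none in untreated cells. Each of the 19 passed the threshold, in a test that rests on the same signals. Their bounds ran from 1.69-fold to 8.64-fold higher in treated cells, with a median of 2.30-fold. For the probes at 1.69-fold and 3.43-fold the bound was the measured ratio, and so no lower limit beyond that estimate. The converse held for 1 probe, which was 1.5-fold lower in treated cells (limma adjusted p = 0.000292). Its bound, too, was its measured ratio. These counts depend on single arrays: 91 probes were well above background in treated RNA alone without array 1, 52 without array 3 and 45 without array 4, and 20 probes in untreated RNA alone without array 2 and 17 without array 4. Leaving out an array relaxes the rule, so the counts can only stay or rise. Cy3, the channel with fewer probes well above background, held the treated RNA on arrays 1 and 3 and the untreated RNA on arrays 2 and 4. Dependence on the array was not told apart from dependence on the dye. Probes that rose by at least 2-fold had a median log2 level of 8.67 in untreated cells and 10.33 in treated cells, and those that fell by at least 2-fold had 10.91 in untreated and 9.65 in treated cells. Of the 230 large rises 165, or 71.7%, were well above background in both RNAs on all 4 arrays, as were 62, or 82.7%, of the 75 large falls. Among all tested probes the share was 87.8%.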

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

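The spread of 11 measures of array quality and of 4 named probes over the arrays was looked at for single arrays far from the rest, which chance would give for about 1 in 20 such measures. Both measures that stood out were of array 4: its median Cy3 signal was 369.3 against 228.3 to 243.3 on the other arrays, and its median Cy5 signal was 238.4 against 115.6 to 135.5. The spike-in controls, whose expected ratios are known to the scanner software, gave observed ratios with a slope on the expected ratios of 0.81 on array 4 and 0.91 to 0.93 on the others. Without array 4, 1756 probes rose and 1762 fell, 238 rose by at least 2-fold and 84 fell by at least 2-fold.

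For 59 of the 14371 tested probes, the log2 ratio differed between the 2 dye orientations at an adjusted p under 0.05 for a dye term on 4 arrays in limma. Of these 59, 15 had also been called for the treatment.

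The spike-in control spots, which enter none of the comparisons, were well above background in both channels for 94.2% of spots on average, against 0% of the 153 negative control spots.

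Turning the ratios of any arrays around gives 8 sign assignments of the 4 arrays, the real one included, which is too few for a share under 0.05. The real assignment gave 4655 calls, and 1 of the 8 assignments gave that many. The highest other number was 130 calls, for the assignment that turns arrays 2 and 4 and so follows the dyes.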

How the results depend on the processing

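No alternative called any of the 4655 probes in the opposite direction. For fits that change only the p-value or the filter this was fixed beforehand, since a probe's mean log2 ratio stays the same. Counts past the threshold moved by over 1.5 times in 6 fits, the first 4 planned. Pairing arrays 1 with 3 and 2 with 4 gave 2641 calls (1419 rose, 1222 fell). Processed signals gave 2612 (1276, 1336), no filter on dim probes 840 (538, 302), and the authors' values 1484 (740, 744) on 6844 probes, which is in part the smaller number tested. Chosen later, the highest p of 3 pairings gave 2637 (1416, 1221) and no normalization 2175 (1582, 593). The cause of the others was not tested. Requiring a 2-fold change left 305 calls. Leaving out each array, in fits with a dye term that count single arrays as replicates, gave 3518 to 4888 calls. Of these, 1756 to 2558 were rises and 1602 to 2330 falls. Rises of 2-fold or more numbered 225 to 249 and falls 61 to 84. Processed signals moved the falls of 2-fold or more to 179 and no normalization to 49, and no other fit moved a count at 2-fold by over 1.5 times. Of the 305 changes, 304 or 305 stayed called wherever they were tested, but for the authors' values (189 of 190) and a filter for both RNAs (227 of 227). Aquantile normalization cannot move a log ratio. The fits on all 4 arrays, the pairings, the eBayes settings, the filters and the block also keep each probe's mean log2 ratio. Their counts at 2-fold can move only through the threshold or the filter, so their stability there says little. The 4 named probes passed the threshold in each alternative that measured them, with ge_Q1_P08983 between -3.42 and -1.57. The authors' values did not cover ge_Q1_P06025 and ge_Q1_P00289 on every array, so these 2 rises were not tested there. The planned replicate block with a dye term was not run, since 4 arrays gave no estimate of its correlation. The block without a dye term gave 3383 rises and 3024 falls at a correlation of -0.53. The gene lists, with mean probes and fry, and the non-coding comparison were not run. Signal over background limits the dim probes, and the correlation of opposite strands ran from 0.39 to 0.47.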

Other observations

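The pairing of probes by strand and the trend with GC content were looked at only after the data were seen, and the spread used for the GC slopes was chosen after the slopes were seen.

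The array carries 15644 pairs of probes that read exactly opposite strands, which is 71.4% of its probes. Neither strand was tested in 9242 pairs, 1 strand in 5381 and both in 1021. Where 1 strand was tested, 775 probes rose and 576 fell. Where both were tested, 38 pairs rose on both strands, 66 fell on both, 10 moved in opposite directions, 308 had 1 strand past the threshold and 599 had none. Re-pairing the probes at random 10000 times gave at most 29 pairs that rose on both strands and at most 34 that fell on both. Which strand belongs to a known gene was not analysed here. Probes in such pairs were tested less often than the others (23.7% against 55.5%), and 25.4% of the tested ones passed the threshold, against 39.8% of tested probes without an opposite-strand partner. The tested paired probes were dimmer, with a median log2 level of 8.87 against 10.26, and were not compared at matched levels.

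Across the 1021 pairs, each entered in both orders, the log2 ratios of the 2 strands correlated at r = 0.43 (permutation p = 1e-04) and rho = 0.46 (permutation p = 1e-04), each the smallest p that 10000 re-pairings can give, and pairs are not independent replicates. The highest r of the re-pairings was 0.13. Copies of 1 strand made during amplification were not told apart from opposite transcripts. The signal levels of the 2 probes of a pair do not give the relative amounts of the 2 strands.

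Large rises were 3.07 times as frequent as large falls at 2-fold or more. The ratio of rises to falls was at least 1.85 under each of 5 scalings, up to 5.73 without normalization. Their median log2 ratios ran only from -0.01 to 0.11, against 0.02 in the main processing. Only ratios centred lower could shrink the excess, and the lowest median, from processed signals, lay close to that of the main processing. The scalings therefore do not decide whether centring is the cause. Processed signals, which gave the 1.85, also differ in background handling. The ratio was 2.66 among probes well above background in both RNAs on all 4 arrays. That argues against loss of 1 RNA below background as the cause. An effect of the treatment itself may give such an excess, as a hypothesis, and the design holds no other treatment to set it against.

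Probes of low GC content fell more often: 26.0% of 2081 tested probes with at most 35% G and C fell, against 7.91% of 4792 with more than 50%. A GC effect tied to the dye, if equal on all arrays, cancels in averages over both dye orientations. The slope of the log2 ratio that remained was 0.048 ± 0.014 (SE with the dye difference removed, n = 4) per 10 percentage points of GC. Mean slopes were 0.085 with treated RNA in Cy3 and 0.012 with treated RNA in Cy5. The SE counts 4 arrays of 2 biological replicates as independent and was chosen after the slopes were seen. It therefore does not decide whether the dye explains the trend. The criterion set before the slopes were computed, 1 sign on all 4 arrays and a mean above 2 SD, was not met. Array 4 had a slope of -0.01, and the SD of the 4 slopes, which holds the dye difference itself, was 0.048. Removing a smooth GC trend narrowed the contrast to 18.5% against 9.02%, and the share of low-GC probes that rose went from 16.5% to 23.8%. The removal shifts the ratios of low-GC probes upward by construction. It therefore does not decide whether the trend is the cause of the falls at low GC. That 84.6% of all falls remained called does not decide this either. For 95% of probes the trend was at most 0.08, and the smallest called change was 0.26 on the log2 scale.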
